A study of Homo sapiens with 6 samples.

How the data were processed

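Total RNA from cultured human primary airway smooth muscle cells, the contractile cells of the airway wall, was measured on 6 whole-transcript microarrays. Cells of 3 donors were split into wells, and each donor gave 1 control array and 1 array after 24 hours in medium with 1 µM BMS493, which the labels describe as an inhibitor of all retinoic acid receptors. A further medium, with DEAB, is named in the design text and is not analysed here.

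The deposited values are on a log2 scale and were made by the authors with RMA (background correction, quantile normalization between arrays and summary per probe set), with the package affy 1.36.1 in R 2.15.1, per the submitters' processing notes. The log2 scale follows from RMA and from the range of the values, since no file header states it. RNA was labelled with biotin, per the labels' protocols. Array files before normalization were not used here, so neither the background correction nor detection above background could be varied or tested, and no probe set can be called absent. RMA compresses changes of probe sets near background, so folds that start from a low signal can be too small. The genome build and the version of the probe grouping are not given in the sources used here, and no coordinates are printed. Precision is limited by the number of arrays, 3 per group.

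The table held 23786 probe sets, 1 per Entrez gene. A single gene symbol was available for 22458 of them from the platform annotation, all found by Entrez number in a current gene table (GRCh38.p14), and 1328 have no symbol here. None had several symbols. Because the cells come from human donors, 41 probe sets of Y-linked genes and XIST were left out of every step, which left 23745. No other filter was applied.

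The model was fitted in limma 3.58.1 under R 4.3.3 with lmFit and eBayes, with donor as a block and the medium as the tested term, two-sided, with Benjamini-Hochberg adjustment over all 23745 probe sets and a threshold of 0.05. It leaves 2 residual degrees of freedom per gene, to which eBayes added 2.16 prior ones. The donor block was chosen before the data were examined, because the growth protocol says that each donor's cells were divided among the wells. The pairing was checked once: the correlation of same-donor deviations from the group means across genes was 0.017, -0.0077 and 0.021 for the 3 donors. Between a control and a BMS493 array of unlike donors it was -0.031 to 0.014. The block thus removed little variance while it cost degrees of freedom. The fit without the block is therefore given beside the main fit as the count of calls in all and in the lists where it changes, and for named genes. Figures were drawn with matplotlib 3.10.9.

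Before the data were examined, 21 gene lists were fixed from general knowledge of retinoic acid signalling, smooth muscle, culture stress and the other cell types that a primary culture could hold. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 21 lists, with an estimated correlation, fry and ranks as alternatives. At a preset correlation camera's p-values measure the spread across genes and not across the 3 donors. With an estimated correlation camera uses the residual degrees of freedom of the fit, 2 with the donor block. The named genes follow a rule of the same date. It takes per direction the 12 largest changes past the threshold that had the same sign in all 3 donors and a mean signal above the 25th percentile of 2.23. To these it adds RARB, CYP26B1, DHRS3, ACTA2, MYH11, TAGLN, RARA and RARG whatever their values, and up to 4 members of each list with the smallest p. Genes outside the rule are marked as such where they are named.

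The test was tried on simulated data with the same 23745 probe sets and the arrays' estimated spread, over 5 runs. Simulated log2 changes of 0.5 were recovered in 1.6% of 250 genes, changes of 1 in 65.6%, changes of 2 in 96.0% and changes of 3 in 97.2%. Beside these changed genes, 37 of 117725 unchanged ones were called, summed over the runs. With nothing changed, 0 genes and 0 lists were called over the 5 runs, and a list shifted by 0.3 was called in 5 of 5 runs. The simulated genes varied independently of one another, and the spread between donors was a chosen value. These runs therefore cannot show how often camera calls a list whose genes move together between wells. Each run also called more genes than the 32 called in the data, which makes the Benjamini-Hochberg cut more lenient. The shares recovered can thus be too high for the data. The alternatives tried were no donor block, centring on array medians, a further quantile normalization, filters on dim probe sets, eBayes with a trend or robust, array weights, an unmoderated paired statistic, adjusted thresholds of 0.1 and 0.25, and leaving out each donor. The design text calls the donors unrelated, and treating the 3 pairs as separate biological samples rests mainly on that label. Control and BMS493 arrays differed about as much within a donor as between donors. The SD of the difference across probe sets was 0.250 to 0.265 and 0.256 to 0.270. On the second principal component (18.6% of the variance) the donors kept the same order in both media. That component was derived from these same arrays, and 3 donors can share an order by chance.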

Results

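Gene expression was compared between airway smooth muscle cells grown in control medium and the same donors' cells grown for 24 hours with 1 µM BMS493, a blocker of all retinoic acid receptors. The series' title frames this as retinoic acid-sufficient against retinoic acid-deficient smooth muscle. There were 3 control and 3 BMS493 arrays, 1 of each per donor. The array medians lay between 3.87 and 3.90 log2 units. Arrays of the same medium correlated across 23745 probe sets at r = 0.9950 to 0.9960, and control and BMS493 arrays of the same donor at 0.9936 to 0.9944, where genes are not independent replicates. Changes below are log2 differences, BMS493 minus control, ± SE from the limma model with donor as a block (n = 3 donors), and levels are RMA log2 signals ± SD (n = 3 arrays).

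BMS493 raised PRG4, which encodes the lubricant glycoprotein lubricin, by 3.92 ± 0.06, MAMDC2 by 3.03 ± 0.08, the matrix protein gene COMP by 2.37 ± 0.06 and the tetraspanin gene TSPAN2 by 2.20 ± 0.09. It lowered DHRS3, a retinaldehyde reductase known to be induced by retinoic acid, by 6.54-fold, from 9.03 ± 0.03 to 6.32 ± 0.06, and RARRES1, a retinoic acid receptor responder, by 4.76-fold, from 5.32 ± 0.13 to 3.07 ± 0.22. In all, 32 genes passed an adjusted p of 0.05, 16 higher and 16 lower. Each moved the same way in all 3 donors, which so small a p from 3 pairs requires. Of the 32 genes, 14 rose and 15 fell by at least 1 log2 unit.

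Further genes that rose were CDKN2B, a cyclin-dependent kinase inhibitor, by 1.87 ± 0.09, the NADPH oxidase gene NOX4 by 1.84 ± 0.06, the cytokine gene IL11 by 1.60 ± 0.09, PLXDC2 by 1.55 ± 0.09, the dermal matrix gene DPT by 1.54 ± 0.05, PTPRN by 1.51 ± 0.07, the smooth muscle myosin heavy chain gene MYH11 by 1.30 ± 0.06 and IGFBP3, a carrier of insulin-like growth factors, by 1.29 ± 0.06. PRG4 started from 1.99 ± 0.04, below the 25th percentile of all probe sets at 2.23, so the ratio of 15.2 depends on the array's background. IGFBP3 was among the brightest, at 10.1 in control and 11.4 with BMS493, a 2.44-fold difference.

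Genes that fell included the antisense transcript PKD1L1-AS1 (-1.88 ± 0.12), for which the strand of the probes is not given in the sources used here, the G protein-coupled receptor genes GPRC5A (-1.88 ± 0.10) and GPRC5B (-1.73 ± 0.06), the scavenger receptor gene COLEC12 (-1.71 ± 0.06) and the integrin gene ITGA8 (-1.62 ± 0.10). The receptor tyrosine kinase gene KIT changed by -1.36 ± 0.06, the urea transporter gene SLC14A1 by -1.30 ± 0.06, LXN by -1.21 ± 0.06, DEPP1 by -1.15 ± 0.06 and SLC16A14 by -1.11 ± 0.06. The adjusted p of the 24 genes ranged from 0.0055 for PRG4 to 0.0498 for RARRES1, PKD1L1-AS1, ITGA8 and PLXDC2 in limma with Benjamini-Hochberg adjustment.

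The number of calls differed between fits. Robust eBayes gave 23 and ended 9 of the 32, among them PLXDC2, RARRES1, PKD1L1-AS1 and ITGA8 (adjusted p = 0.055). Without the donor block 331 genes passed, 148 higher and 183 lower, and they included all 32, while leaving out any 1 donor, which leaves 1 residual degree of freedom, gave 0 calls in limma with 1866 to 2052 genes at an unadjusted p under 0.05. With all donors 2574 genes had an unadjusted p under 0.05, where 1187 would be expected by chance.

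**Figure D1:**
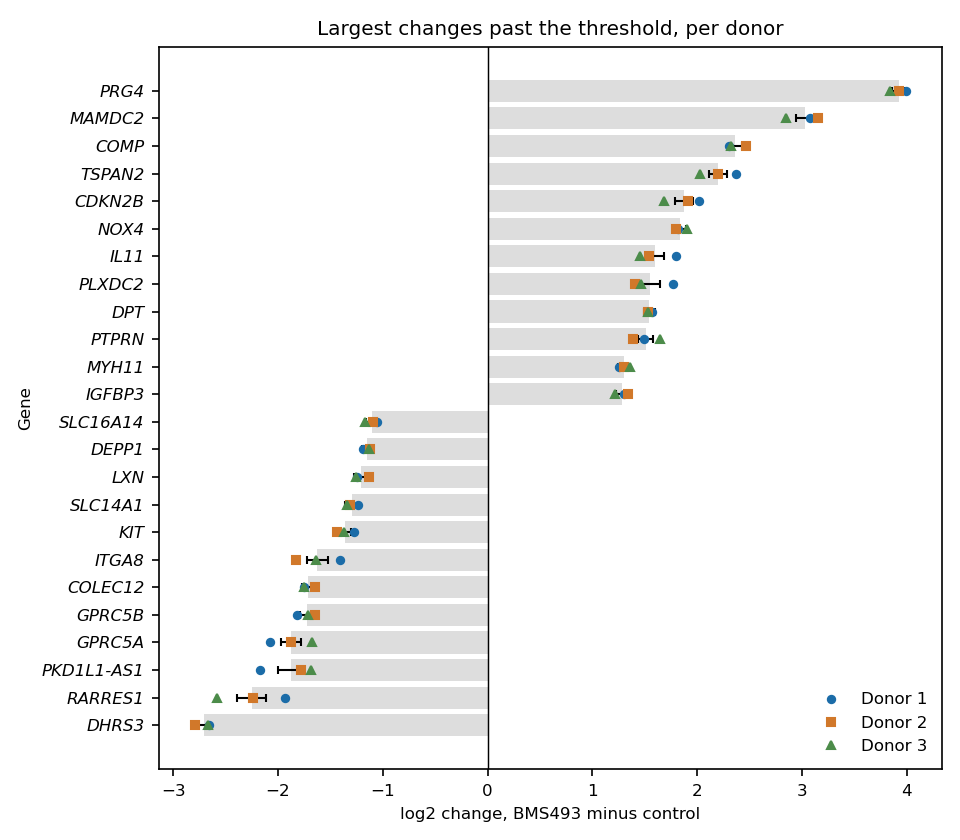
Log2 change (BMS493 minus control, horizontal axis) of the 12 largest increases and 12 largest decreases past the threshold, 1 gene per line. Grey bars are means over 3 donors with SE and symbols are the single donors. They lie on the same side of 0 for every gene, as the naming rule required. PRG4 is at 3.92 and DHRS3 at -2.71.

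The list of genes that respond to retinoic acid shifted downward with BMS493 in camera (median -0.13, camera adjusted p over the 21 lists 7.8e-06), a call lost with an estimated correlation (adjusted p = 0.20). Of 24 measured members, 2 fell (DHRS3 and RARRES1), 0 rose and 22 did not pass over all genes; without the donor block 5 fell and 0 rose. Robust eBayes ended the call of RARRES1. In all 9 fell and 0 rose adjusted over the list alone. The adhesion molecule gene ICAM1, also a member of the cytokine list, differed by -1.08 ± 0.10 (adjusted p = 0.085, and 0.0079 without the donor block). The receptor genes themselves differed by -0.83 ± 0.11 for RARB, itself a classical target (adjusted p = 0.15), -0.47 ± 0.06 for RARG (adjusted p = 0.12, and 0.0485 without the block) and -0.08 ± 0.06 for RARA (adjusted p = 0.71). CYP26B1, which degrades retinoic acid, differed by -0.31 ± 0.09 from a control signal of 4.06, close to the array medians (adjusted p = 0.39). Genes of retinoid synthesis and transport gave 0 calls among 31 (camera adjusted p = 0.54); the smallest p belonged to the retinol dehydrogenase genes RDH11 (0.36 ± 0.07) and RDH10 (-0.28 ± 0.06). Among 29 HOX genes, which pattern the body axis and include known retinoic acid targets, 0 passed, with HOXB3 at -0.43 ± 0.08 and HOXB5 at -0.29 ± 0.06 (camera adjusted p = 0.48). HOXB3 passed without the block (adjusted p = 0.0499).

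The list of contractile genes of smooth muscle shifted upward in camera (median 0.13, camera adjusted p = 9.5e-05), a call lost with an estimated correlation (adjusted p = 0.20). Of 29 measured members, MYH11 and the intermediate filament gene SYNM (1.00 ± 0.06) rose, ITGA8 fell and 26 did not pass; without the donor block 7 rose and 1 fell, and with robust eBayes SYNM and ITGA8 did not pass (adjusted p = 0.055). With adjustment over the list alone 8 rose and 2 fell. The calponin gene CNN1 differed by 0.90 ± 0.06 (adjusted p = 0.0503, and 0.0027 without the block), and the smooth muscle actin gene ACTA2 by 0.73 ± 0.06, from 9.89 ± 0.02 to 10.63 ± 0.02 (adjusted p = 0.062, and 0.0022 without the block). TAGLN, another actin-associated marker, differed by 0.27 ± 0.06 (adjusted p = 0.27). The 2 that fell adjusted over the list alone were ITGA8, a smooth muscle integrin, and SYNPO2 (-0.23 ± 0.06), which is outside the naming rule and was chosen after its value was seen. The receptors and calcium handling genes of airway smooth muscle did not pass camera as a list (camera adjusted p = 0.24): 0 of 48 passed over all genes, and adjusted over the list alone the phospholipase gene PLCB4 (0.49 ± 0.06) and the potassium channel gene KCNMA1 (0.56 ± 0.08) were higher and the G protein regulators RGS4 (-0.60 ± 0.06) and RGS2 (-0.68 ± 0.11) lower. These 4 also passed without the donor block.

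**Figure D2:**
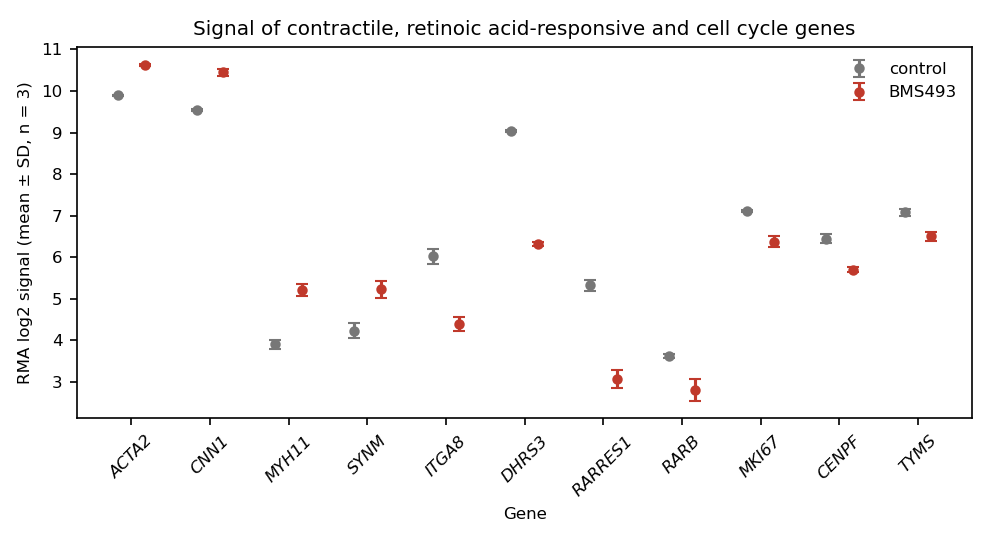
RMA log2 signal (vertical axis, mean ± SD of 3 arrays) of 11 genes in control (grey) and BMS493 (red). ACTA2, CNN1, MYH11 and SYNM lie higher with BMS493, and ITGA8, DHRS3, RARRES1, RARB, MKI67, CENPF and TYMS lie lower; MYH11 went from 3.90 to 5.21.

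The cell cycle list had the smallest p of the 21 lists in camera (adjusted p = 8.2e-27), a call lost with an estimated correlation (adjusted p = 0.12). The estimate was -0.0088 here, -0.0092 for the retinoic acid list and -0.031 for the contractile list, all below the preset 0.01. A higher correlation between genes was therefore not what ended these calls. Of 40 measured members 0 passed over all genes, but 32 fell and 0 rose adjusted over the list alone, and the list's median was -0.44, with medians of -0.36, -0.46 and -0.46 in the 3 donors. The proliferation marker MKI67 differed by -0.75 ± 0.08, the kinetochore gene CENPF by -0.75 ± 0.08, the thymidylate synthase gene TYMS by -0.58 ± 0.06 and the spindle gene DLGAP5 by -0.57 ± 0.06, with adjusted p between 0.085 and 0.096 over all genes. Without the donor block 12 members passed over all genes, all lower, these 4 among them.

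Matrix genes shifted upward as a list (median 0.07, camera adjusted p = 9.5e-05, adjusted p = 0.20 with an estimated correlation). Over all genes 0 of 52 passed, without the donor block 7 were higher and 2 lower, and adjusted over the list alone 12 were higher and 4 lower. The proteoglycan gene VCAN differed by 0.74 ± 0.06, and the basement membrane collagen genes COL4A2 by 0.63 ± 0.05 and COL4A1 by 0.95 ± 0.09. COL8A1 differed by 0.50 ± 0.06. These 4 were among the 7 higher without the donor block, with adjusted p of 0.0027, 0.0036, 0.0055 and 0.021.

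Signalling lists held members that differed in both directions and did not pass camera. In the TGF-beta and BMP list of 51 genes, 0 passed over all genes, without the donor block 5 were higher and 3 lower, and adjusted over the list alone 6 were higher and 4 lower. BMP6, a secreted ligand, differed by 1.66 ± 0.12, the TGF-beta target PMEPA1 by 1.32 ± 0.10, the activin subunit gene INHBA by 0.50 ± 0.06 and the signal transducer SMAD3 by -0.63 ± 0.07. The list's camera adjusted p was 0.54. In the IGF list of 24, IGFBP3 rose, the ligand gene IGF1 differed by 2.11 ± 0.16, from 4.28 ± 0.31 to 6.38 ± 0.17 (adjusted p = 0.062, and 0.0058 without the block), and IGFBP6 and PIK3R1 by -0.57 ± 0.07 and -0.44 ± 0.07. Adjusted over the list alone 3 were higher and 4 lower; the list's median (-0.03) and camera direction were negative and its mean (0.08) and fry direction positive (camera adjusted p = 0.87). In the WNT list of 39, 0 passed over all genes. The WNT antagonist gene SFRP1 differed by -0.91 ± 0.06, the receptor gene FZD8 by 1.07 ± 0.10, WNT2B by -0.45 ± 0.06 and WNT3 by 0.31 ± 0.06 (camera adjusted p = 0.54). Adjusted over the list alone 1 was higher and 2 lower. BMP6, PMEPA1, INHBA, SMAD3, IGFBP6, PIK3R1, SFRP1, FZD8 and WNT2B passed without the donor block.

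The list of cytokine and chemokine genes shifted downward in camera (adjusted p = 0.0016), a call lost with an estimated correlation (adjusted p = 0.20). Of 36 measured members, CCL2, a monocyte chemoattractant, fell by 1.05 ± 0.06 on the log2 scale (adjusted p = 0.0498), IL11 rose and 34 did not pass; without the donor block 5 fell and 1 rose, and with robust eBayes CCL2 did not pass (adjusted p = 0.055). Adjusted over the list alone 6 fell and 1 rose, and the interleukin receptor gene IL1R1 differed by -0.66 ± 0.06 (adjusted p = 0.085, and 0.011 without the block). Interferon response genes gave 0 calls among 33, with IRF1 at -0.45 ± 0.06 and a camera adjusted p of 0.076; adjusted over the list alone 1 fell.

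Among the stress and metabolic lists, unfolded protein and amino acid stress genes shifted up by a median of 0.10 with 0 of 29 members past the threshold of 0.05 over all genes or over the list alone, the cystine transporter gene SLC7A11 leading at 0.33 ± 0.06 (camera adjusted p = 4.0e-05, adjusted p = 0.20 with an estimated correlation). Cholesterol synthesis genes shifted up by a median of 0.05 (medians of -0.02, 0.11 and 0.09 in the 3 donors), with the sterol enzyme genes MSMO1 at 0.54 ± 0.08 and SQLE at 0.35 ± 0.06, both higher adjusted over the list alone and 0 of 22 over all genes. That list's camera adjusted p was 0.013, against an adjusted p = 0.39 with an estimated correlation and 0.17 in camera without donor 2. Hypoxia and glycolysis genes gave 0 calls among 27, and without the donor block 2 higher and 1 lower. The vasodilator peptide gene ADM was at -0.70 ± 0.06 and the glucose transporter gene SLC2A1 at 0.44 ± 0.06. Adjusted over the list alone 3 were higher and 1 lower (camera adjusted p = 0.067, and 0.046 without the block). Immediate early genes, which respond to handling and growth factors, gave 0 calls among 28 over all genes, 2 higher and 3 lower without the donor block, and 3 higher and 5 lower adjusted over the list alone. NR4A1 was at 0.51 ± 0.07, MYC at -0.41 ± 0.06, FOSL1 at -0.43 ± 0.07 and FOS at -0.43 ± 0.07 (camera adjusted p = 0.76). Of the genes named in these lists, MSMO1, SQLE, ADM, SLC2A1, NR4A1, MYC and FOSL1 passed without the donor block.

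The lists of markers of other cell types did not pass camera. For fibroblasts and pericytes DPT rose, and the remaining 23 members did not pass over all genes; PI16 differed by 0.86 ± 0.06 and the pericyte gene ABCC9 by -0.58 ± 0.06. Adjusted over the list alone 2 were higher and 1 lower, and the camera adjusted p was 0.055, against 0.046 without the block and a fry adjusted p of 0.0042. In the cartilage, fat and nerve list of 20, COMP rose and the cartilage proteoglycan gene ACAN differed by -0.86 ± 0.11, the only members past the threshold adjusted over the list alone; its median was -0.00036 and its mean 0.08 (camera adjusted p = 0.73). In the immune list of 23, KIT fell and 22 did not pass (camera adjusted p = 0.44). Epithelial markers gave 0 calls among 21, with the keratin gene KRT8 at -0.62 ± 0.10 (camera adjusted p = 0.48, fry adjusted p = 0.023), and endothelial markers 0 among 21, with the receptor gene FLT1 at -0.36 ± 0.07 (camera adjusted p = 0.54). PI16, ABCC9 and ACAN passed without the donor block. The epithelial and endothelial lists had 0 members past the threshold adjusted over the list alone.

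**Figure D3:**
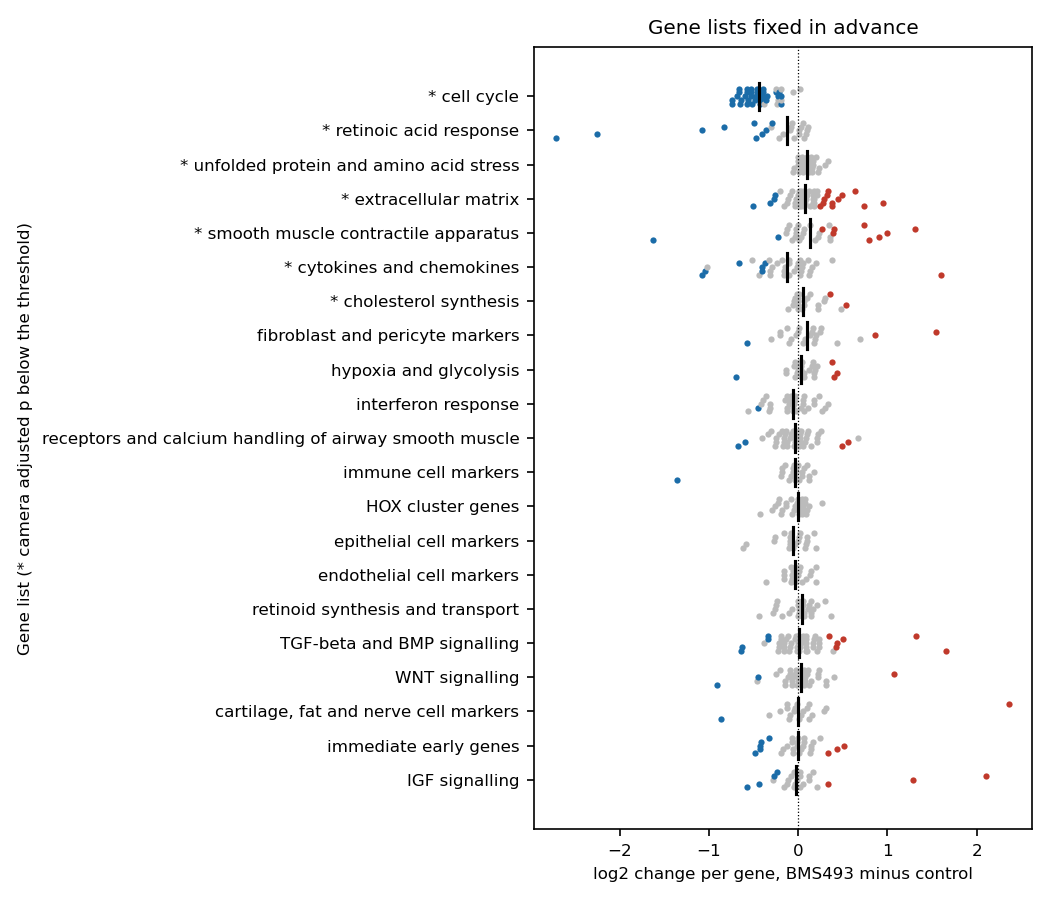
Log2 change of every measured member (points, horizontal axis) of the 21 gene lists, with the list's median as a black bar. Red and blue points are higher and lower members past the threshold adjusted over the list alone, grey points did not pass, and the 7 lists with a star passed camera at the preset correlation (0 with an estimated correlation); the cell cycle list has its median at -0.44.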

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

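Alternatives named in this part were chosen before the data were examined. The count of 32 changed genes moved to 331 with no replicate block for the donor pairing, 76 with arrays centred on their medians, 64 after quantile normalization of the deposited values, 94 and 377 without probe sets below the 25th percentile and below the median, 304 with a mean-variance trend in eBayes, and 159 and 732 at adjusted thresholds of 0.1 and 0.25. All 32 were among the genes called in each of these, which holds by definition at the looser thresholds. The ordinary paired statistic without moderation gave 0 calls, with 1966 genes at an unadjusted p under 0.05. Without each replicate in turn limma gave 0 to 0 calls. Robust eBayes gave 23 and array weights 35. None of the 103 named genes changed direction under any alternative fit run on it. The block, trend, robust and filter alternatives leave the mean difference as it is. Direction could change only with renormalized arrays, array weights or a donor left out. Leaving out a donor could not change it for genes with the same sign in all donors. Robust eBayes ended 9 calls, each with the same log2 change and an adjusted p that went from 0.0498 to 0.055. They were PLXDC2, RARRES1, PKD1L1-AS1, ITGA8, SYNM and CCL2. The others, APCDD1L, PTGIS and RASSF2, are outside the naming rule and were chosen after their values were seen. The retinoic acid response list kept its direction and its call in 13 alternatives without an estimated correlation, with adjusted p from 4.1e-07 to 0.0062. The trend and robust settings of eBayes do not enter camera, so there the camera adjusted p (7.8e-06) was that of the main test by construction. All of the 13 but fry (adjusted p = 0.0062) kept the preset correlation. With an estimated correlation the list kept the call without the block (camera adjusted p = 0.039) and lost it with the block (0.20). The number of lists past the threshold, 7, was 0 with an estimated correlation, 3 with no block and an estimated correlation (cell cycle 0.0081, retinoic acid response 0.039, contractile apparatus 0.046), and 6 to 7 without each replicate. Beside those given in the results, changes of calls were gains for fibroblast markers (0.041 with centred arrays) and interferon response (0.017 without the dimmest probe sets) and a loss for cholesterol synthesis in fry (0.10). Apart from construction (fewer genes tested, fewer degrees of freedom), the cause of these differences was not tested. Changes of 0.5 log2 units were mostly out of reach, as the simulations showed, and signal over background is unknown.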

Other observations

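The test of TGF-beta-induced genes used a list written before the values of its members were looked at but after the top genes had been seen, and the test of cartilage markers was chosen after the result was seen. The split count and the test against matched lists were set before their results were seen.

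Among genes that passed only without the donor block, the following are outside the naming rule, were chosen here after their values were seen and were not tested as a group. TSPAN13 was 2.07 higher with BMS493 (adjusted p = 0.0055 without the block, 0.075 with it), the matrix linker gene HAPLN1 0.95 higher and the gene of the adhesion molecule MCAM 0.93 higher. Lower were the anticoagulant receptor gene THBD at -0.97, the plasminogen activator gene PLAT at -0.87, the protease inhibitor gene A2M at -0.86 and the guanylate cyclase subunit gene GUCY1B1 at -0.81. Of the 8 genes past the threshold with the block that the naming rule did not take as largest, TNFAIP6 (1.16), APCDD1L (1.20), SYNM (1.00) and RASSF2 (0.91) rose. The prostacyclin synthase gene PTGIS (-0.97), the calcification inhibitor gene MGP (-1.01), TNIK (-1.01) and CCL2 (-1.05) fell.

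The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 32 genes with the donor block, and the highest of the other splits called 0; only 1 split, the real one, called as many. The real split parts all 3 pairs, as do 3 others, which had 702 to 802 genes at an unadjusted p under 0.05 against 2574. The other 6 part 1 pair and had 1336 to 1832. Every split but the real one mixes control and BMS493 arrays in both groups, so differences between the media add to its residual spread. Their 0 calls are therefore not a measure of what chance alone would give.

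The lower cell cycle list was set against 10000 random lists matched on mean signal. Its median of -0.44 lay below all of them, of which the central 95% lay between -0.05 and 0.04. The list thus stood apart from genes of like signal drawn independently of one another. The lowest random median was -0.097, which argues against a shift of all genes of that signal level as the source of the -0.44 in these values. Whether such a shift was there before normalization cannot be decided, because quantile normalization within RMA removes most of it. Whether the wells differed in cell density at harvest is not known from these data and stays open beside an effect of the drug on proliferation.

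COMP, NOX4, IL11, CDKN2B and MYH11, all higher with BMS493, are also known TGF-beta-induced genes, so a hypothesis is that TGF-beta activity was higher in the BMS493 wells. In a separate list of 24 TGF-beta-induced genes, 22 measured, the median log2 change was 0.34 (95% bootstrap bounds 0.13 to 0.53). Of these 16 were positive, and camera gave an unadjusted p = 5.4e-08 (unadjusted p = 0.027 with an estimated correlation). The camera p-values of the fixed lists are instead adjusted over all of those lists. Unadjusted, with an estimated correlation, camera gave p = 0.0059 for the cell cycle list and p = 0.032 for the retinoic acid list. The 0.027 therefore does not set the TGF-beta-induced list apart from fixed lists that lost their call. The bounds come from resampling the genes of the TGF-beta-induced list and not the donors, so they do not measure the spread between donors. Adjusted over that list alone 13 were higher, among them PLOD2 (0.64 ± 0.06) and BHLHE40 (0.70 ± 0.06), and 2 lower, EDN1 (-0.22 ± 0.06) and LMCD1 (-0.32 ± 0.08); these 4 are outside the naming rule and were chosen after their values were seen. Of that list 0 passed over all genes and 7 without the donor block. In the fixed TGF-beta and BMP list, which did not pass camera (adjusted p = 0.54), the TGF-beta targets PMEPA1 and TGFBI differed by 1.32 ± 0.10 and 0.35 ± 0.06 and passed without the donor block, while the feedback genes SMAD7 and SKIL did not pass, at 0.0034 ± 0.08 and -0.09 ± 0.06. TGFBI, SMAD7 and SKIL are outside the naming rule and were chosen after their values were seen. The result is consistent with, but does not establish, such a rise, and direct repression of the same genes by retinoic acid receptors stays open. The 7 other cartilage markers of the fixed list did not rise as COMP did. Their median was 0.012 (bounds from resampling these genes -0.32 to 0.12), the highest was 0.31, and ACAN was lower. PRG4 (3.92) and HAPLN1 (0.95, past the threshold only without the donor block), which cartilage also expresses, rose and were not part of the test. A larger share of cartilage cells is therefore argued against by the 7 markers only and is not excluded.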
